A study of Zea mays with 4 samples.

How the data were processed

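RNA was measured in the central starchy endosperm, the inner storage tissue of the maize kernel, of the inbred line B73 at 6 days after pollination (DAP). Per the labels, the tissue was cut out of kernel sections by laser-capture microdissection, RNA was treated with DNase and amplified, and barcoded Illumina libraries were sequenced together in 1 flow cell lane. The labels number 4 replicates of 1 group, so no comparison between groups was possible. Nothing in the labels says whether the replicates came from different plants, ears or kernels, so the SDs and p-values below measure the spread between these 4 libraries, which may be technical.

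The deposited values are a scaled signal per gene model, with 110028 gene models in each library. The values themselves show that the authors' scaling made every library sum to 4773346, which is the mean of the library totals recovered below. No division by gene length was seen. Per the submitters' processing notes, bedtools was used, with neither its version nor its role stated. The aligner, genome build, annotation and strand setting are not given in the sources used here. In each library all non-zero values were whole multiples of the smallest non-zero value, within a tolerance of 0.01 of a read, so 1 read was worth 1.39, 0.879, 1.00 and 0.871 units in replicates 1 to 4. Dividing by this step gave 100% whole numbers and totals of 3432952, 5428283, 4754684 and 5477465 reads. In replicate 3 the step of 1.00392 lies close to 1, the step that rounding to whole numbers would give. All its non-zero values were whole multiples of 1.00392 within 3.1e-05 of a read, which argues against such rounding. As a precaution, tests on reads are also given without replicate 3. Such tests were added after the values were seen, because the deposited unit is not counts.

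Levels are given as RPM, the reads of a gene per 1000000 reads summed over all gene models in a library, computed here from the deposited signal. A read can have been counted for more than 1 overlapping model, so RPM is a share of counted reads, not of molecules. Log values are log2(RPM + 0.5) unless another pseudocount is named, which understates ratios of genes at low levels. The smallest level that 3 reads represent was 0.874, 0.553, 0.631 and 0.548 RPM in replicates 1 to 4, and 0.157 RPM over the 19093384 reads of all libraries. Exact 95% Poisson intervals and these floors cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Without transcript lengths, levels of different genes are compared as read shares, so a long transcript yields more reads than a short one at equal abundance.

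Gene names came from a RefSeq gene table of assembly Zm-B73-REFERENCE-NAM-5.0, through the older gene model identifiers that it lists as synonyms. It named 18786 of the 110028 models and 15197 of the 37643 models above 0 in any library. None of its coordinates were used. Before the data were examined, 12 gene lists with 151 symbol entries, 14 lists defined by product description, 20 gene pairs, the tests, the alternatives and the rule for named genes were fixed. Of the symbol entries, 93 matched a single model, 46 matched no model and 11 matched more than 1 model and were left out. The entry mrp1 was also left out, because the table gives its model a second, unrelated name. The 14 description lists could not be used, because the table holds no product descriptions, and 8 lists by name pattern were added after the data were seen. They cover zeins, ribosomal proteins, tubulins, fermentation enzymes, heat shock proteins, light harvesting proteins, basal layer antifungal proteins (BAP) and MADS-box factors.

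Named genes are the 20 with the highest mean RPM that carry a name, the 4 highest members and the lowest member of each fixed list, all members of the tested pairs, the 10 named genes with the largest log2 ratio of the highest to the lowest library at a mean of at least 10 RPM, and any list member that differed between libraries beyond counting error and by over 4-fold. Other genes are said to have been chosen after their values were seen. An item that this rule takes is not reported here.

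A gene was called detected in a library at 1 RPM or more. Agreement was measured by Pearson's r and Spearman's rho across genes with a mean of 1 RPM or more, and by edgeR's common biological coefficient of variation on recovered reads with an intercept-only design. The main measure of variation was the SD of log2 values at a mean of 10 RPM or more. A chi-square test of recovered reads against TMM effective library sizes, with Benjamini-Hochberg adjustment at 0.05 over the 16516 genes kept by edgeR's filter, compared these libraries and not conditions. That filter asks for a minimum level in every library. It drops genes near 0 in 1 library and also genes low in all, such as mads47 with 6 to 13 reads, so counts for lists are also given without it. The median log2 level of each list was placed among 10000 random lists of the same size, drawn from the genes detected in at least 1 library. Differences between list medians within libraries were tested with an exact two-sided sign-flip permutation test, whose smallest possible p with 4 libraries is 0.125. Gene pairs were tested with limma on log2 ratios within libraries, two-sided, with Benjamini-Hochberg adjustment over the 11 pairs in which both genes matched. In this test limma draws the variances of the pairs toward each other, so p-values and intervals do not rest on a pair's own SD alone. No paired analysis across groups applied.

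Pairwise chi-square tests of recovered reads called between 1098 genes, for replicates 1 and 2, and 6393 genes, for replicates 2 and 4, of 16516, so no pair of libraries was treated as 1 library deposited again. In simulated counts for the chi-square test over 16516 genes, changes of 1.5, 2, 4 and 8-fold in 1 library were recovered in 66%, 90%, 100% and 100% of 50 genes each with a mean of 5 RPM or more, with 0.055% of the 16316 unchanged genes called. These counts were drawn with Poisson error only, which the test itself assumes. The simulation therefore checks the computation and gives no error rate for amplified reads. In 500 simulated pairs with no difference the pair test called 2.8%, and it called 99.2% of 250 pairs with a log2 ratio of 1. All simulated pairs had the same SD, the median of the observed SDs, which ran from 0.21 to 1.52 over the tested pairs. These shares therefore do not describe tested pairs with larger SDs.

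Alternatives were other detection levels, pseudocounts of 0.1 and 2 RPM, no filter on low values, DESeq2 size factors and dispersion, raw totals, TMM scaling, other backgrounds for the random lists, means in place of medians, and leaving out each replicate in turn. Added after the data were seen were tests without replicate 3, the lists with models of the entries that matched more than 1 model put back, and the mrp1 model put back. Scaling by transcript length was not run, because no lengths of the models in the files were used here, and removal of ribosomal RNA and organelle genes was not run, because the files do not name them. Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.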

Results

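Transcripts were measured in the central starchy endosperm of B73 maize kernels at 6 DAP, an early stage of endosperm development, in 4 replicate libraries of laser-captured tissue. Recovered depth was 3432952, 5428283, 4754684 and 5477465 reads on gene models in replicates 1 to 4. Values below are mean RPM ± SD over the 4 libraries (n = 4) unless replicates are given singly.

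The 20 most abundant named genes included some with known roles in translation, glycolysis, fermentation and the cytoskeleton, beside genes known only by locus numbers, and no enrichment was tested. The glycine-rich protein gene grp1 (GRMZM2G080603) stood first at 24675 ± 4167 RPM. The translation elongation factor gene EF1-A reached 6588 ± 1593 RPM and the initiation factor gene tif-4A3 3140 ± 399 RPM. Among enzymes of glycolysis, enolase (eno1) reached 4492 ± 790 RPM, the glyceraldehyde-3-phosphate dehydrogenases GAPC3 and gpc4 2228 ± 446 and 2176 ± 66.1 RPM, and aldolase (ald1) 1929 ± 377 RPM. Alcohol dehydrogenase 1 (adh1), which regenerates NAD+ in fermentation, reached 4471 ± 849 RPM.

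Cytoskeletal genes among the 20 highest were the alpha-tubulin gene TUA2 (GRMZM2G153292), which the reference also names TUA1, at 4455 ± 299 RPM, the beta-tubulin gene tub5 at 2700 ± 430 RPM and the profilin gene PRO4 at 2374 ± 430 RPM. The exoglucanase gene exg1 stood at 2873 ± 202 RPM, TA1 at 2716 ± 129 RPM and fl3, which encodes a PLATZ-type transcription factor of the endosperm, at 2092 ± 525 RPM. Further genes among the 20 carried only locus numbers, led by LOC100277357 at 7869 ± 1014 RPM and LOC100281766 at 4761 ± 1101 RPM. The level of grp1 was shared by an unnamed model, GRMZM5G836166, at 24672 RPM, with a difference of at most 0.0129% in any library, so reads of the pair cannot be assigned to either. Of 11030 models with a mean of at least 50 reads, 232 had counts identical to those of another model.

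At 1 RPM or more, 21196, 21406, 21470 and 20382 genes were detected in replicates 1 to 4, a mean of 21114 ± 502. Of these, 18604 were detected in all 4 libraries and 23827 in at least 1. The 10 most abundant gene models, with grp1 and GRMZM5G836166 counted separately despite their near-equal values, took 8.98 ± 1.07% of reads, the top 100 took 22.2 ± 1.33% and the top 1000 took 53.4 ± 1.66%.

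Genes of starch synthesis formed a list with a few members at moderate levels and several near 0. Dull1 (du1), a starch synthase, had 97.6 ± 3.48 RPM, the plastidial starch phosphorylase pho1 42.1 ± 6.14 RPM, starch synthase 1 (ss1) 27.4 ± 3.42 RPM and the pullulanase-type debranching enzyme zpu1 14.95 ± 9.19 RPM. In contrast, waxy1 (wx1), the granule-bound starch synthase of the endosperm, was at 0 in every library, while its paralog gbss2a stood at 3.10 ± 0.606 RPM. With wx1 set at the floor of 0.157 RPM over all libraries, gbss2a was 19.7-fold higher, a ratio that leaves out the counting error of both genes. The ADP-glucose pyrophosphorylase subunit genes sh2 and bt2, whose enzyme supplies ADP-glucose for starch, were at 0.460 ± 0.158 and 0.778 ± 0.420 RPM. Of the 12 matched members, 6 averaged 1 RPM or more and 5 averaged 10 RPM or more.

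The median member of the starch list had 2.03 ± 0.286 RPM, and its log2 level lay at percentile 1.19 of random lists of detected genes. Drawn from all gene models instead, percentile 99.6 was found, and from genes detected in all libraries percentile 0. Entries that matched more than 1 model were left out of this list and included abundant ones, chosen here after their values were seen: GRMZM2G032628, which carries both names ae1 and sbe1 of starch branching enzymes, had 209 ± 34.6 RPM, and GRMZM2G106213, one of the models named agp2 for an ADP-glucose pyrophosphorylase subunit, had 107 ± 33.0 RPM. With such models put back, the median log2 level of the list moved from 1.19 to 3.46.

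Genes on the list for sucrose cleavage and uptake, which also holds fructokinases, were mostly low. The fructokinase frk2 reached 41.0 ± 10.6 RPM and the vacuolar invertase ivr2 11.8 ± 3.35 RPM, while frk1 stood at 1.65 ± 1.23 RPM and the cell wall invertase incw3 was at 0 in every library. The sucrose synthase genes sus1 and sus2 had 0.827 ± 0.451 and 0.528 ± 0.457 RPM, and shrunken1 (sh1), the sucrose synthase of the filling endosperm, was at 0 in replicates 1 to 3 and at 1.28 RPM in replicate 4. The cell wall invertase gene mn1, known for its role in the basal transfer layer, had 0.583, 2.95, 4.42 and 0.365 RPM in replicates 1 to 4. Of the 11 matched members, 4 averaged 1 RPM or more, and the list's median lay at percentile 0.0075 of random lists of detected genes, against 98.5 with random lists from all gene models.

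Regulators of storage protein genes were present while zein transcripts were near 0. Opaque11 (o11), a bHLH factor of the endosperm, had 153 ± 8.48 RPM, the zinc finger factor nkd1 65.9 ± 28.8 RPM and its duplicate nkd2 21.8 ± 5.57 RPM, and the bZIP factors ohp1 and ohp2 35.9 ± 1.26 and 17.5 ± 3.41 RPM. The lowest of the 6 matched regulators, mads47, had 2.13 ± 0.446 RPM, and the list stood at percentile 92.6. The models named o2 and pbf1, factors that activate zein genes, matched more than 1 identifier each and lay between 0 and 2.73 RPM, and with them put back the median log2 level of the regulators moved from 4.86 to 1.77. Of 19 models with zein names, a list added after the data were seen, 17 were at 0 in every library, and gz27 had 1.31 ± 1.70 RPM. Zein genes are near-identical copies, so a level of 0 can also reflect how reads with several matches were counted.

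Of the factors behind opaque and floury kernels, fl3 had the 2092 RPM given above, the endoplasmic reticulum chaperone gene bip1 had 235 ± 61.6 RPM, bip2 16.3 ± 6.73 RPM and o7 47.9 ± 3.11 RPM. The zein gene fl2 was at 0 in every library. This list of 5 lay at percentile 96.4 of random lists.

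Cell cycle genes were among the most abundant lists. The replication clamp genes pcna2 and pcna1 had 260 ± 39.5 and 230 ± 54.8 RPM, the replication helicase gene mcm3 110 ± 11.98 RPM and the cyclin-dependent kinase gene cdka1 104 ± 20.7 RPM. All 13 matched members averaged 1 RPM or more, with 10 of them at 10 RPM or more, and the lowest, the kinase inhibitor gene krp1, had 3.42 ± 0.711 RPM. The list lay at percentile 99.4 of random lists. The mitotic cyclin genes cyca1 and cycb1, chosen after their values were seen, had 29.2 and 15.9 RPM in replicate 4, against 45.2 to 50.8 and 28.8 to 33.7 RPM in the other libraries.

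In the list of chromatin factors and imprinted genes, the DNA methyltransferase genes zmet2 and zmet3 had 149 ± 24.6 and 93.0 ± 14.9 RPM. The Polycomb genes fie1, which is imprinted in maize endosperm, and mez2 had 53.2 ± 5.87 and 19.8 ± 2.07 RPM, and nrp1 was lowest at 0.291, 0.368, 2.94 and 1.83 RPM in replicates 1 to 4, a range of over 4-fold beyond counting error in the chi-square test without the filter. The 8 members averaged 1 RPM or more, though nrp1 averaged 0.828 RPM without replicate 3, and the list lay at percentile 83.8. In the hormone list all 6 members averaged under 1 RPM. The cytokinin oxidase gene ckx10 was highest at 0.862 ± 0.528 RPM, tar3 had 0.5002 ± 0.413 RPM and acs6 0.0921 ± 0.184 RPM, while ckx1 and vp1 were at 0 in every library. The list lay at percentile 0 of random lists of detected genes, which follows from members that average under the detection level, and at 50.3 of random lists from all gene models.

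**Figure D1:**
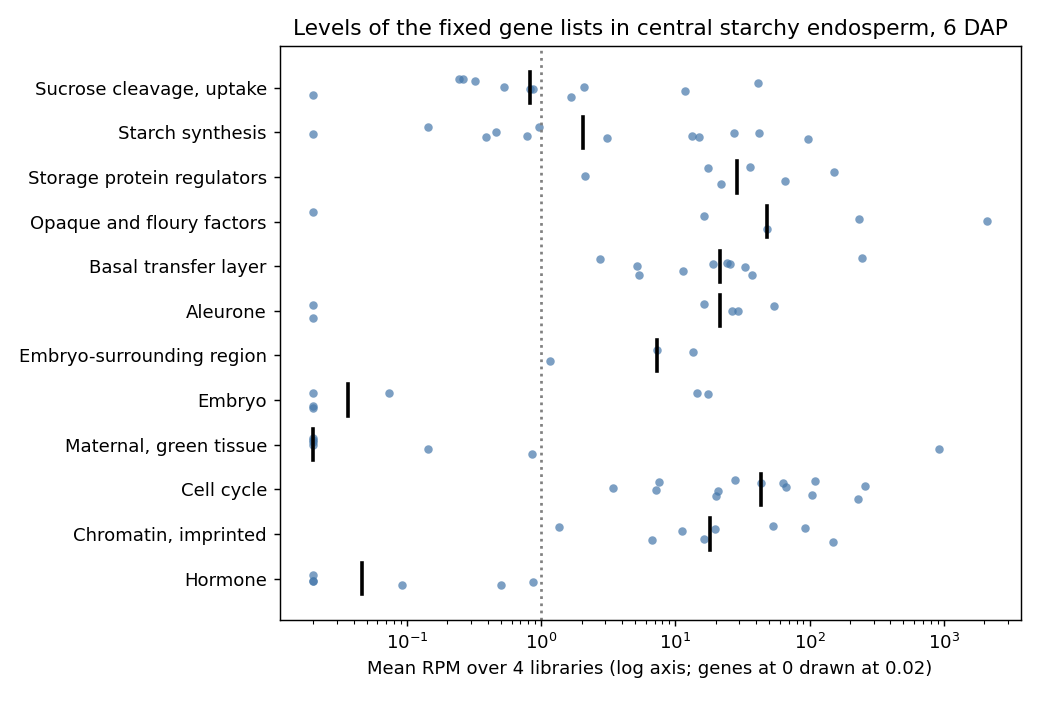
Mean RPM over 4 libraries on a log axis for each matched member of the 12 lists fixed before the data were examined, 1 point per gene, with a black bar at the median of the members' means and a dotted line at 1 RPM. Cell cycle genes all lie above 1 RPM and hormone genes all lie below it, and members at 0 are drawn at the left edge.

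Genes of the basal endosperm transfer layer (BETL), which takes up nutrients at the kernel base, were present in replicates 1 to 3 and mostly low in replicate 4. Marker betl2 had 191, 436, 329 and 27.2 RPM in replicates 1 to 4, betl10 had 30.6, 59.9, 55.7 and 2.19 RPM, and betl9 had 18.1, 52.7, 57.6 and 3.10 RPM. Over the 10 matched markers the summed level was 322, 668, 575 and 70.7 RPM. In contrast, ebe1 had 26.2, 22.1, 25.9 and 27.2 RPM, and tcrr1, the lowest member, had 1.46, 3.68, 5.89 and 0 RPM. The list lay at percentiles from 2.72 to 96.7 of random lists in single libraries.

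Markers of the embryo-surrounding region (ESR), the endosperm next to the embryo, were also low in replicate 4. Here esr2 had 20.4, 17.9, 14.7 and 1.28 RPM, esr3 7.57, 14.6, 6.52 and 0.365 RPM, and esr6 1.46, 1.47, 1.68 and 0 RPM. Of 6 matched genes on the list for the aleurone, the outer endosperm layer, 4 were present in every library. These were sal1 at 54.2 ± 8.24 RPM, the calpain gene dek1 at 29.1 ± 4.74 RPM, the receptor kinase gene cr4 at 26.3 ± 2.05 RPM and vpp1 at 16.4 ± 1.59 RPM. The other 2, the anthocyanin regulator r1 and c1, which was chosen after its value was seen, were at 0 in every library. The aleurone list lay at percentile 84.4.

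Of the 6 embryo markers, the oleosin gene ole1 had 17.6 ± 5.19 RPM and the homeobox gene wox2a 14.4 ± 4.64 RPM, kn1 had 0.0728 ± 0.146 RPM, and glb2 and wox5b were at 0. Among 7 genes of maternal and green tissue, only the pyruvate phosphate dikinase gene ppdk1, which is also transcribed in endosperm, averaged 1 RPM or more, at 1055, 1150, 917 and 551 RPM in replicates 1 to 4. The floral genes zag2 and zag1 had 0.859 ± 0.581 and 0.144 ± 0.0970 RPM, and bde1 and rbcs1 were at 0. Both lists, with medians near 0, lay at percentile 0 of random lists of detected genes, and at 50.6 (embryo) and 45.5 (maternal and green tissue) of random lists from all gene models.

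**Figure D2:**
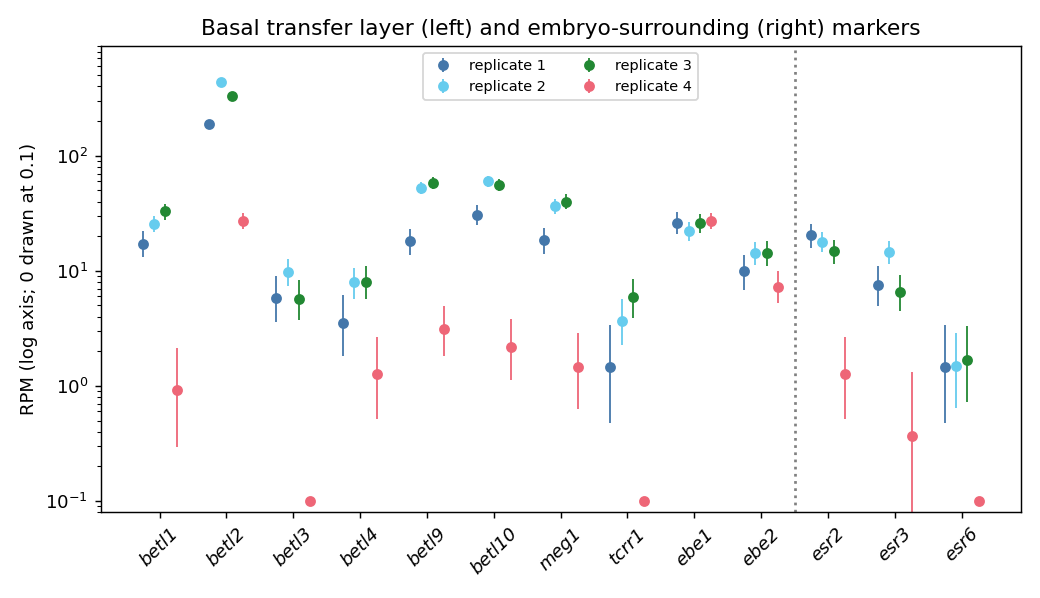
RPM on a log axis for 10 BETL and 3 ESR markers in each of the 4 libraries, with exact 95% Poisson intervals for counting error only, and values of 0 drawn at 0.1. Replicate 4 (red) lies below the other libraries for most markers, at 27.2 RPM for betl2 against 191 to 436 RPM, but not for ebe1.

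Within libraries, the median log2 level of the starch list was lower than that of the BETL list by a mean difference of -2.53 ± 1.72 (exact sign-flip permutation p = 0.13, adjusted p = 0.156). It was -2.81, -3.46 and -3.83 in replicates 1 to 3 but -0.02 in replicate 4, and the mean without replicate 4 was -3.36. The difference to the aleurone list was -3.18 ± 0.16, in 4 of 4 libraries (exact permutation p = 0.13, adjusted p = 0.156), and to the ESR list -1.19 ± 1.79, lower in 3 of the 4 libraries (exact permutation p = 0.25, adjusted p = 0.25). Starch genes stood above the embryo list by 2.11 ± 0.07 and above the maternal and green tissue list by 2.19 ± 0.13, each in 4 of 4 libraries (exact permutation p = 0.13, adjusted p = 0.156). The median of the maternal and green tissue list was at 0 RPM in every library, and that of the embryo list in all but replicate 1. The pseudocount therefore sets the size of both differences, and their SDs mostly reflect the starch list. With 4 libraries no p can go below that value of 0.13, so none of these 5 differences could pass 0.05. With models of entries that matched more than 1 model put back, the mean differences to the BETL, aleurone and ESR lists were -0.26, -0.91 and 0.97 and those to the embryo and maternal lists 4.28 and 4.46. With these models the BETL difference had opposite signs between libraries, as the starch list lay above the BETL list in replicate 4. Without replicate 4, and without these models, the ESR difference was -2.05. The size of each difference thus rests on which models are included, and for the embryo and maternal lists also on the pseudocount. Of the means, only the ESR difference changed direction.

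Of 11 gene pairs tested within libraries, 6 differed between members (limma, adjusted p under 0.05). The chaperone gene bip1 exceeded bip2 by a log2 ratio of 3.86 (95% interval 3.34 to 4.37, adjusted p = 9.3e-06), and the Polycomb gene fie1 exceeded fie2, at 11.1 ± 3.23 RPM, by 2.24 (1.64 to 2.83, limma adjusted p = 0.00023). The factor nkd1 exceeded nkd2 by 1.52 (0.94 to 2.10, limma adjusted p = 0.0015), ohp1 exceeded ohp2 by 1.03 (0.49 to 1.58, limma adjusted p = 0.0069), and the retinoblastoma-related gene rbr1, at 20.03 ± 4.49 RPM, exceeded rbr3, at 7.53 ± 3.43 RPM, by 1.41 (0.58 to 2.24, limma adjusted p = 0.0098). Each of these 5 held the same sign in 4 of 4 libraries. The ratio of rbr1 to rbr3 had an SD of 0.83, the largest of these 5, so its call rests most on the variances that limma drew together. That call was lost without replicate 2 (log2 ratio 1.15, limma adjusted p = 0.056). For wx1 against gbss2a the fitted log2 ratio was -2.83 (-3.36 to -2.30, limma adjusted p = 3.8e-05), a value set by the pseudocount because wx1 was at 0.

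The other 5 pairs did not pass. The ratio of mn1 to incw1, at 0.244 ± 0.244 RPM, was 1.48 (0.15 to 2.81, limma adjusted p = 0.053), and it passed without replicate 1 (1.97, limma adjusted p = 0.00062) and without replicate 4 (1.86, limma adjusted p = 0.00011). Both calls rest on variances that limma drew together over the pairs, since the ratio's own SDs there were 1.41 and 1.61. Without replicate 4 all pairs had the same interval width, and the ratio lay above 0 in 2 of 3 libraries. These calls therefore do not show a difference beyond the spread of this pair. The ratio of sh1 to sus1 was -0.88 (-1.72 to -0.04, limma adjusted p = 0.058) and of sh1 to sus2 -0.48 (-1.68 to 0.71, limma adjusted p = 0.37). Only replicate 4 had reads of sh1, so without it the ratios of -1.23 (limma adjusted p = 0.0042) and -1.11 (limma adjusted p = 0.0080) are set by the pseudocount and give no bound. The ratio of sh2 to bt2 was -0.35 (-1.03 to 0.33, limma adjusted p = 0.31). For the Polycomb genes mez1, at 16.3 ± 4.03 RPM, and mez2 it was -0.30 (-0.91 to 0.31, limma adjusted p = 0.31). Genes of these pairs other than mez1 and mez2 averaged 2.08 RPM or less, near the floor of 3 reads in single libraries.

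**Figure D3:**
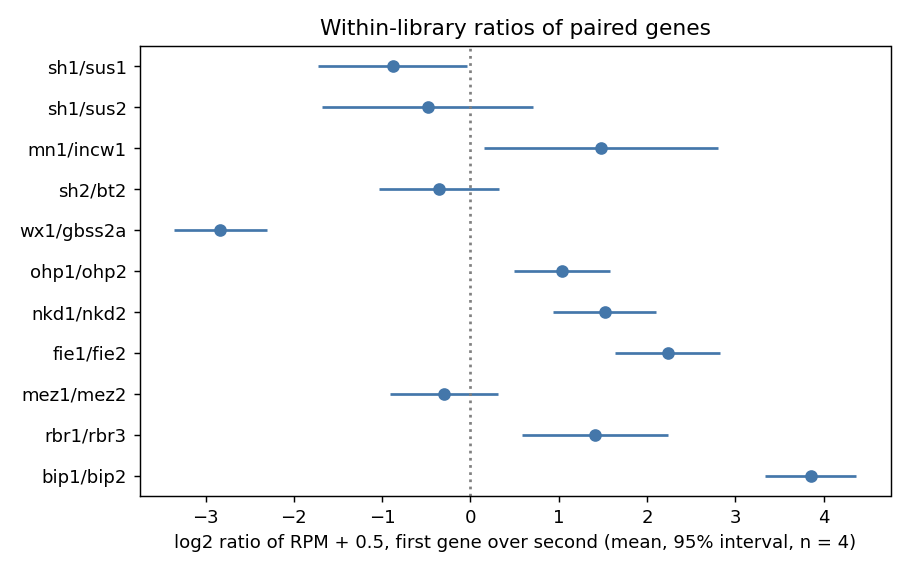
Log2 ratio of RPM + 0.5 of the first gene over the second within libraries, as the mean (point) and 95% interval (line) over 4 libraries, for 11 gene pairs. The ratio of bip1 to bip2 is highest at 3.86. Limma intervals that cross the dotted line at 0 belong to sh1/sus2, sh2/bt2 and mez1/mez2. The intervals use variances drawn together over the pairs, which narrows those of pairs with large SDs. Those of mn1/incw1 (SD 1.52) and sh1/sus1 (SD 0.84) therefore do not by themselves set these ratios apart from 0. In each of them 3 of 4 libraries had the same sign.

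Replicates correlated across 21181 genes with Pearson's r from 0.944, for replicates 2 and 4, to 0.973, for replicates 2 and 3, and Spearman's rho from 0.941 to 0.973, with a mean r of 0.960. Genes are not independent replicates, so these describe agreement only. Pairs with replicate 4 had r from 0.944 to 0.956 and the other pairs from 0.966 to 0.973. The SD of log2 levels had a median of 0.216 over 11272 genes (interquartile range 0.142 to 0.324), with 99 genes above 1. On recovered reads edgeR's biological coefficient of variation was 0.191, and 0.120 without replicate 4.

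The chi-square test on recovered reads found 7293 of 16516 genes (44.2%) to differ between libraries beyond counting error, and 2934 without replicate 4, 6874 without replicate 3. Without the filter it called 7780 of 37643 genes (20.7%), many of them with too few reads to be called. Lists differ in how many members are near 0, so the list counts that follow are set against neither share. Of the BETL list 9 of 10 members differed when no filter was applied, as did 9 adjusted over the list alone, and 8 of the 9 ranged over 4-fold. With the filter, which kept 5 of the 10, 4 differed. For the ESR list 2 of 3 differed without the filter and 3 adjusted over the list alone. Without the filter, and equally adjusted over the list alone, 9 of 13 cell cycle genes, 6 of 8 chromatin genes, 4 of 12 starch genes, 5 of 11 sucrose genes, 3 of 6 storage regulators, 3 of 5 opaque and floury factors, 2 of 6 embryo markers, 1 of 7 maternal and green tissue genes, 0 of 6 aleurone markers and 0 of 6 hormone genes differed. With the filter 1 aleurone marker, sal1, passed.

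The 10 named genes with the largest range between libraries were all lowest in replicate 4. They included the models GRMZM2G088896 and GRMZM2G094054, both named meg2 after a maternally expressed gene family of the transfer layer, at 154, 264, 178 and 8.22 RPM and at 140, 229, 169 and 8.95 RPM in replicates 1 to 4. The cystatin gene cc8 had 68.2, 140, 85.6 and 4.56 RPM, BET1 (betl1 in the list) had 17.2, 25.6, 32.8 and 0.913 RPM, MEG1 had 18.4, 36.3, 39.96 and 1.46 RPM, and betl10 is given above. The other 4 carried only locus numbers, led by LOC100279046 at 13.7, 57.1, 46.5 and 0.548 RPM.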

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

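All tests of explanations in this part were chosen after the results were seen. An outlying library was sought by Dixon's criterion (0.829 for 4 libraries) among 138 results, of which 14 had one, 10 of them in replicate 4. Chance gives about 1 in 20, a share that does not apply to 4 of the 14, sh1 and the embryo, hormone and light harvesting medians, in which the other 3 libraries were tied at the value of 0 reads. The 138 results also overlap, as list medians share genes with single-gene results. They include genes picked for a large range between libraries, such as the meg2 models, so that share is only a rough guide.

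In replicate 4, the ESR marker esr2 lay apart at 1.28 RPM and esr6 at 0 RPM, the models named meg2 at 8.22 and 8.95 RPM, the aleurone genes sal1 and vpp1 at 42.0 and 14.1 RPM, and the aleurone list's median log2 level at 4.22, each below the other libraries. Above the other libraries in replicate 4 lay exg1 at 3175 RPM, the homeobox gene wox2a at 21.4 RPM and sh1 at 1.28 RPM. The floral gene zag2 was lowest in replicate 1, at 0 RPM. Dixon's criterion takes no account of counting error, and not all of these genes differed beyond it. In the chi-square test vpp1 did not (adjusted p = 0.88), and sal1 passed with the filter (adjusted p = 0.032) but not without it (0.059). Without the filter esr6 (chi-square adjusted p = 0.16) and zag2 (0.44) did not pass, though esr6 passed when adjusted over the ESR list alone. Near the floor, the median log2 level of the embryo list was highest in replicate 1 at -0.67, of the hormone list in replicate 2 at -0.77 and of the light harvesting list in replicate 3 at -0.75.

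The BETL markers low in replicate 4 form the first pattern. Their median log2 deviation from the other libraries was -3.66 (range -4.39 to 0.07), while over all genes at 10 RPM or more it was -0.10, which argues against depth or scaling. Random loss of transcripts is argued against too, since 0.428% of 13783 other genes at similar levels lay over 8-fold lower. RNA of neighbouring basal cells in replicates 1 to 3 may explain it but cannot be told apart from other causes: 7 of 9 markers at 3 RPM or more (77.8%) were at least 2-fold lower in replicate 4 than in any other library, with the most abundant, betl2, at 27.2 against 191 to 436 RPM, but ebe2 was lower by less than that (7.30 against 9.90 to 14.3 RPM), ebe1 was not lower (27.2 against 22.1 to 26.2 RPM), and how many of the 10 markers the captured cells also express is not known from these libraries. Laser capture would remove such cells only as far as the cut edges kept them out, and no biological explanation was tested, as there is 1 group.

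Replicate 4 also stood apart over many genes. Among 11272 genes at 10 RPM or more, 706 (6.26%) had an outlying library, near the share chance gives, but 457 of them had it in replicate 4 (323 low and 134 high), against 102, 78 and 69 in replicates 1 to 3. In this paragraph each gene model was counted by itself, also where its reads equalled those of another model. Depth is argued against, since replicate 2, sequenced to nearly the depth of replicate 4 (5428283 and 5477465 reads), had 17.1% as many. RNA of neighbouring cells in replicates 1 to 3 cannot be told apart from other causes: of the outlying genes over 2-fold apart in replicate 4, 96 were low and 6 high (94.1% low), but the BETL marker ebe1 did not follow, and the genes higher in replicate 4 depend on scaling. By over 0.5 log2, 1324 lay above and 1501 below after TMM scaling, with 442, 516 and 353 above in replicates 1 to 3, against 830 above and 2121 below in RPM, with 535, 682 and 354 above in replicates 1 to 3, so that the number above was at the least 1.22 times the largest in another library. The labels give all libraries the same age and protocol, so no biological explanation was tested.

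The near-equal values of grp1 and GRMZM5G836166, 24675 and 24672 RPM, form the last pattern. They differed by at most 0.0129% in any library, a value consistent with the same reads having been counted for both models. Whether the models overlap or are copies was not tested, as no annotation of the models was used here.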

How the results depend on the processing

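Of 239 checks of the 34 main results, 211 kept their direction and side of the threshold or moved by less than the spread between libraries. The models of entries that matched more than 1 model, and tests without replicate 3, were chosen after seeing the data. Except where a cause is given, the cause was not tested. The mean r was 0.973 without the filter and 0.947 with a pseudocount of 0.1 RPM. Lists near 0 have log2 levels set by the pseudocount by construction. At pseudocounts of 0.1 and 2 RPM these were -0.56 and 1.37 for sucrose genes, 0.87 and 1.95 for starch genes, -3.08 and 1.02 for embryo, -3.32 and 1.0 for maternal and green tissue and -3.13 and 1.02 for hormone genes. At 2 RPM the aleurone list had 4.47 and the chromatin list 4.35. With models of entries that matched more than 1 model put back, levels were 3.46 for starch, 1.77 for storage regulators, 4.03 for opaque and floury factors and -0.44 for hormone genes. The difference of starch and ESR lists turned to 0.97 that way (exact permutation p = 0.25) and to 0.0079 with means in place of medians (exact permutation p = 1.0). The ratio of mn1 to incw1 passed at a pseudocount of 2 RPM (0.74, limma adjusted p = 0.0090, range over its alternatives 0.00011 to 0.23). There its own SD was 0.79, and limma again drew the variances of the pairs toward each other. Leaving out each replicate in turn gave a coefficient of variation of 0.120 to 0.219, 2934 to 6874 genes beyond counting error, and log2 ratios of -1.23 to -0.56 for sh1/sus1, -1.11 to -0.066 for sh1/sus2, 1.04 to 1.97 for mn1/incw1 and 1.15 to 1.79 for rbr1/rbr3. The lowest coefficient of variation and the lowest count came without replicate 4, and the lowest rbr1/rbr3 ratio without replicate 2. Of 586 further checks on single genes, percentiles and added lists, 554 moved by less than the spread between libraries, and the other 32 are percentiles against other backgrounds or levels of added lists at another pseudocount. With the mrp1 model put back, which was at 0, the BETL level was 3.58 against 3.72. No paired analysis was possible because there is 1 group. Lists by transcript length and without ribosomal RNA or organelle genes were not run. Depth limits statements on genes below 0.874 RPM in replicate 1 and 0.548 RPM in replicate 4.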

Other observations

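Lists added after the data were seen show further groups. Of 30 ribosomal protein models, 28 averaged 1 RPM or more, with a list median of 204 ± 17.8 RPM, at percentile 100 of random lists. Tubulin genes reached a median of 211 ± 37.9 RPM over 11 models, also at percentile 100, with TUB1 at 1234 ± 55.6 RPM and TUBA6 at 790 ± 108 RPM beside the TUA2 and tub5 named above. Among 4 fermentation genes, pyruvate decarboxylase pdc3 had 123 ± 14.3 RPM and adh2 15.7 ± 1.29 RPM, against 4471 RPM of adh1, with a list percentile of 95.5. Heat shock genes ranged widely, from hsp70-4 at 1344 ± 469 RPM and HSP90-2 at 574 ± 42.9 RPM to hsp18c at 0, and the list of 14 lay at percentile 44.0.

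Light harvesting genes were mostly at or near 0, with 6 of 12 at 0 in every library and PSBQ at 57.6 ± 4.44 RPM as the exception, and the list lay at percentile 0 of random lists of detected genes, as did the zein list, but at 58.0 and 49.1 of random lists from all gene models. Of 30 MADS-box models 10 averaged 1 RPM or more, led by zmm19 at 46.6 ± 4.12 RPM, MADS69 at 30.5 ± 2.10 RPM and zmm16 at 14.8 ± 3.50 RPM, and the list lay at percentile 0 of the former and 99.8 of the latter. All 5 BAP models, of which 1 is the betl2 model under another name, were at least 2-fold lower in replicate 4 than in any other library, such as bap-3a at 8.16, 18.2, 10.9 and 0 RPM and bap-1a at 5.53, 13.3, 13.3 and 0.548 RPM, and the list lay at percentiles from 0.485 to 75.2 in single libraries. The zein gene gz27 went the other way, at 0.583, 0.184, 0.631 and 3.83 RPM in replicates 1 to 4, as did the small heat shock gene hsp18f at 13.4, 13.6, 9.04 and 42.2 RPM. Of 141 genes whose libraries ranged over 4-fold at a mean of 10 RPM or more, 110 were lowest in replicate 4. These are counts of gene models, some with near-equal reads, so they are not counts of independent genes. Such a pair, chosen after its values were seen, is GRMZM2G080263 with 98, 571, 754 and 25 reads in replicates 1 to 4 and AC203847.3_FG009 with 98, 569, 752 and 25.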
